A study of Mus musculus with 9 samples.

How the data were processed

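The material was RNA from mouse liver in 9 libraries, 3 each from the normal, model and TA groups, with every group taken from the labels. Per the labels, total RNA was extracted with Trizol and libraries were made with the NEBNext Ultra RNA kit, and the submitters' processing notes name the mm9 build. The aligner, the counting tool, the use of strand, the amount of tormentic acid, the time of collection and the sex of the mice were not given in the sources used here. The deposited expression table held, per the file headers, read counts for 21898 genes in every library, and these raw counts were used for all tests. The authors also gave FPKM values in that table, which equalled the counts scaled by the listed gene length and by the library total to within 3.54 ppm and were not used further. The authors' deposited comparison tables gave a fold change as a ratio of group means, made with DESeq per the file names. The same deposited tables gave p-values and adjusted p-values by the authors, whose settings were not stated. These tables covered model against normal and TA against model, and were used only for the number of genes called at an adjusted p under 0.05. Of the genes in the table, 21794 had an Ensembl identifier of GENCODE release M21, but only 514 had the same start as on GRCm38, so the build of the listed coordinates was not settled. Coordinates printed here are those of GENCODE M21 on GRCm38. 1 line of the expression table had been emptied for this work and was not used.

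Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr over the 3 groups (minimum count 10, minimum total 15), which left 13200 genes. Library sizes were scaled with TMM factors, and 1 quasi-likelihood model with group as the only factor was fitted to all 9 libraries. The comparisons were model against normal, TA against model and, as a secondary one, TA against normal. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, and a gene was called at an adjusted p under 0.05 with no minimum fold. Rose and fell are used for called genes only. Every adjusted p of a gene comes from edgeR quasi-likelihood tests unless another tool is named. The replicate numbers were not used as a block, since no label ties them to an animal or day, and 1 of 9 same-number pairs of libraries had a correlation over 0.1 after removal of the group means.

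Named genes followed a rule set before the data were examined, as were the comparisons, the tests, the 31 gene lists and other ways of processing. The rule took, for each main comparison, the 8 largest rises and 8 largest falls (4 each for TA against normal) among called genes with at least 10 CPM in the higher group and no overlap between the groups, without clone-type names or pseudogenes. For each list it took up to 4 members with the smallest p and the member with the smallest p in the other direction. For changes in both main comparisons it took the 8 genes with the largest opposite and the 4 with the largest same-sign changes. Folds of genes with at most 3 counts in a group were given as ratios of scaled counts with 95% counting intervals, or as bounds against a floor of 3 counts over the group. Those intervals cover counting error only.

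The 31 lists, written from general knowledge of liver biology, covered fatty acid uptake and lipid droplets, fatty acid synthesis, cholesterol synthesis and uptake, and bile acid synthesis and transport. They also covered fatty acid oxidation and PPAR alpha targets, methionine, choline and one-carbon metabolism, NRF2 and glutathione genes, the unfolded protein and integrated stress response, and inflammatory cytokines, chemokines and NF-kB targets. Further lists held interferon-stimulated genes, acute phase and complement genes, and markers of macrophages and monocytes, Kupffer cells, lipid-associated macrophages, neutrophils, T and NK cells, and B and plasma cells. Others held stellate cell and matrix genes, cholangiocyte, liver endothelial and hepatocyte markers, pericentral and xenobiotic enzymes, male-biased and female-biased liver genes, the circadian clock and the cell cycle. The last ones held nuclear genes of oxidative phosphorylation, gluconeogenesis, glycolysis and insulin response, apoptosis, p53 and ferroptosis genes, immediate early genes, and markers of adipose tissue, muscle, pancreas, gut and red cells. Of 846 genes in the lists, 827 were found in the table, 772 were tested and 33 of these stood in more than 1 list. Lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01 between genes, and adjusted over the 31 lists. For each list the number of called members was also computed with p-values adjusted over the list alone.

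Other ways of processing, also set beforehand, were DESeq2 size factors, library totals without factors, no filter on low counts, a stricter filter (10 counts in every library of a group), fits of only the 6 libraries compared, a replicate block, a minimum change of 2-fold, DESeq2 1.42.0, limma-voom, and leaving out each library in turn. For lists, camera with an estimated correlation and fry were also set. Other splits of the libraries were also counted. For the genes called in both main comparisons, counts were simulated in 50 data sets with no effect, since the model libraries enter both with opposite signs. KEGG terms written in the deposited table were tested among called genes by 1-sided Fisher exact tests in Python 3.11.15, over 262 pathways of 10 to 300 genes and a background of 5794 genes. These pathway tests were chosen after the data were seen.

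The depth of 13710002 to 16475794 counts per library put a floor of 3 counts at under 1 CPM, and the spread between libraries, not depth, set the precision. The methods were tested on simulated data with the spread of these libraries and 200 changed genes. In model against normal, edgeR called 2.99% of 1.5-fold, 47.8% of 2-fold and 92.4% of 4-fold changes, with 5 calls among the unchanged genes. For TA against model these shares were 7.46%, 44.8% and 86.4%, and for TA against normal 2.99%, 38.8% and 89.4%. Many changes of less than 2-fold would thus be missed. The list test called the moved list in each comparison and 0 of the 20 unmoved ones. With independent genes and random lists, that run does not measure false calls of lists whose genes move together. Reads of gene families with near-identical copies (Mup, Cyp2, Serpina1, Saa, haemoglobin and Gst genes) are divided among copies with an error that was not measured here.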

Results

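Liver RNA from C57BL/6 mice was sequenced in 9 libraries. Mice had been assigned at random to 3 groups, and each group was represented by 3 libraries. The normal group was the reference and, per the labels, received saline. Whether the other groups received saline or a vehicle was not given in the sources used here, so their differences from the normal group may include it. The model group ate an MCD (methionine- and choline-deficient) diet, which produces fatty liver. The TA group ate the same diet and received tormentic acid (TA), a plant triterpenoid, at the dose that the labels call high. The counts per library summed to 13950065 to 16475794 in the normal group, 15519086 to 16086294 in the model group and 13710002 to 16464308 in the TA group. The p-values measure only the spread between these 9 libraries, since the labels do not say that each library came from a separate mouse.

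The 3 groups separated along the first principal component of log2 CPM (counts scaled to library size), which carried 65.3% of the variance. Normal libraries scored between -87.5 and -72.4, TA libraries between -0.600 and 11.3, and model libraries between 42.7 and 92.5. Model replicate 2, at 42.7, lay apart from the other model libraries. Correlations across genes within groups were 0.979 (normal), 0.955 to 0.979 (model) and 0.960 to 0.973 (TA), where genes are not independent replicates. Mitochondrial transcripts took 4.92%, 12.5% and 15.4% of counts in TA replicates 1 to 3. They took 7.36% to 11.6% in model and 6.45% to 7.80% in normal libraries. Without TMM factors, haemoglobin CPM summed to 173 ± 41.0, 259 ± 49.3 and 413 ± 126 in normal, model and TA libraries (mean ± SD, n = 3). With them, CPM of Hbb-bs and Hba-a1 overlapped between normal and model.

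**Figure D1:**
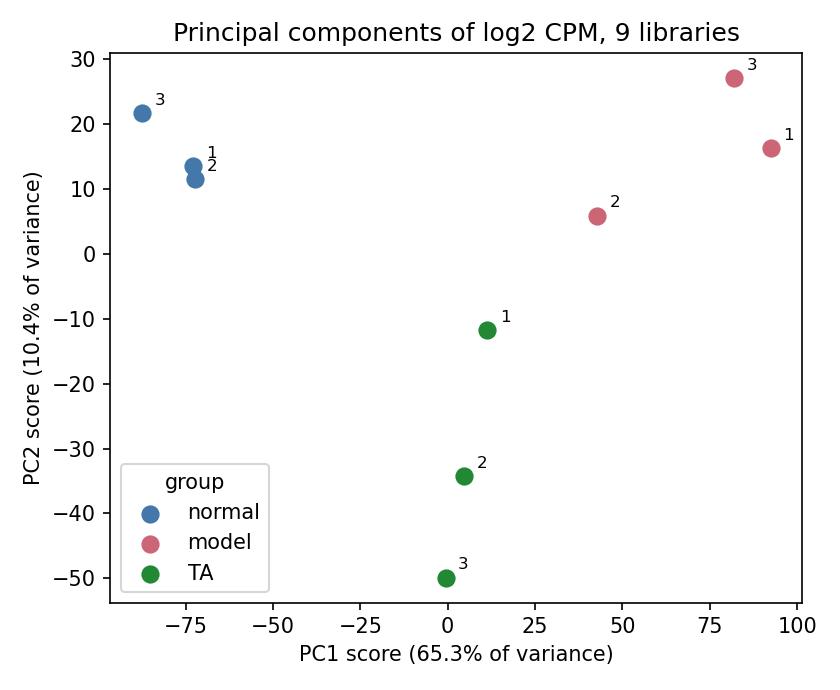
Scores of the 9 libraries on the first (65.3% of variance) and the second (10.4%) principal component of log2 CPM, coloured by group and numbered by replicate. The 3 TA libraries lie between the normal and the model libraries on the first axis, from -0.600 to 11.3.

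The direction of small changes depended on how the libraries were scaled. The trimmed mean of M-values (TMM) factors were 0.833 ± 0.00888 in the normal, 1.34 ± 0.137 in the model and 0.900 ± 0.102 in the TA group (mean ± SD, n = 3). With library totals alone, the median gene moved by 0.688 on the log2 scale for model against normal, by -0.577 for TA against model and by 0.108 for TA against normal. All changes given here are therefore relative to the median gene, and each ± after a log2 fold change is the standard error of the fit with n = 3 libraries per group.

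Model against normal compared livers of mice on the MCD diet with those of the reference group. Macrophage, matrix and cell cycle transcripts were more abundant in the model livers, and transcripts for lipid synthesis, bile acid synthesis and other hepatocyte functions were less abundant. The tests of these lists were called with a preset correlation and gave adjusted p = 0.271 to 0.358 with an estimated correlation. Mmp12, a macrophage elastase (ENSMUSG00000049723, chromosome 9, 7344381 to 7369499 on GRCm38), rose from 0.289 ± 0.251 to 422 ± 19.03 CPM (mean ± SD), a log2 fold change of 10.50 ± 0.46 (adjusted p = 3.30e-07). Scd1, the liver's main stearoyl-CoA desaturase (ENSMUSG00000037071, chromosome 19, 44394455 to 44407879 on GRCm38), fell from 11590 ± 4930 to 134 ± 69.1 CPM, a log2 fold change of -6.43 ± 0.61 (adjusted p = 1.38e-05). Of 13200 genes tested, 6344 changed, 3357 higher and 2987 lower in the model group. The authors' deposited table called 5420 genes, and 5236 of these were also called here in the same direction. With library totals alone 8100 genes were called and 89.7% of them were higher, against 52.9% with TMM factors.

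The largest rises, besides Mmp12, included Gpnmb, a lysosomal glycoprotein of lipid-laden macrophages, at 7.998 ± 0.39 (adjusted p = 4.26e-07). The surface protein gene Ly6d rose by 7.09 ± 0.57 (adjusted p = 4.61e-06) and the leukocyte metalloproteinase gene Adam8 by 6.34 ± 0.39 (adjusted p = 1.19e-06). Vsig8 had no counts in the normal group and was at least 215-fold higher in the model group, against a floor of 3 counts over the group. Cyp2a4, a female-biased cytochrome P450, had 1 count in the normal group and a ratio of 3138 (95% counting interval 563 to 124000). That count lay in normal replicate 1, and the gene stood at 141.1, 40.05 and 54.3 CPM in model replicates 1 to 3. Mmp7, an epithelial metalloproteinase, had 1 count in the normal group, in normal replicate 2, and a ratio of 528 (94.6 to 20890). Mmp7 stood at 28.04, 0.272 and 10.09 CPM in model replicates 1 to 3, so replicate 2 lay near the normal libraries. Cyp2b9, another female-biased P450, rose by 6.11 ± 1.28 (adjusted p = 0.00241), or by 5.505 without normal replicate 3. Its normal counts all lay in normal replicate 1 (0.958 CPM), and without that library it was listed at 0 in the normal group. Mmp12 stood at 9.89 without normal replicate 3 and Ly6d at 7.98 without normal replicate 2. The calls of Mmp7 and Cyp2b9 ended with limma-voom, at adjusted p = 0.173 and 0.192, over ranges of 1.90e-05 to 0.173 and 2.28e-05 to 0.192.

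The largest falls were in genes of male liver. Hsd3b5, a steroid dehydrogenase, fell from 337 ± 21.6 to 0.134 ± 0.121 CPM, a log2 fold change of -11.30 ± 1.21 (adjusted p = 3.12e-05). The major urinary protein genes Mup15, Mup7, Mup12, Mup17 and Mup19 fell, with log2 changes between -11.24 and -9.62 (adjusted p between 9.78e-05 and 0.000674). These Mup genes are near-identical copies, so the division of reads among them is uncertain. Normal replicate 1 stood apart from the other normal libraries for several of them, with Mup15 at 55.3, 1226 and 1172 CPM and Mup17 at 83.7, 2562 and 1657 CPM in normal replicates 1 to 3. Elovl3, a fatty acid elongase, fell by 7.93 ± 1.33 (adjusted p = 0.000655). Without model replicate 2 the changes were -12.17 for Hsd3b5, -13.40 for Mup7, -12.77 for Mup12, -10.95 for Mup17, -11.45 for Mup19 and -10.78 for Elovl3. Mup12 also stood at -8.47 without normal replicate 2 and -9.295 without model replicate 3, and Mup17 at -9.17 without normal replicate 2. The counts listed under Pitx3, a homeodomain factor gene, were 3 in the model group and 717-fold lower (95% counting interval 245 to 3480). The end of Pitx3 overlaps that of Elovl3 on the other strand (46135685 and 46135694 on GRCm38), so with strand use not stated these counts may be Elovl3 reads.

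Many lipid and bile acid synthesis genes fell. In the fatty acid synthesis list, 16 fell and 1 rose of 20 (16 fell and 1 rose adjusted over the list alone). The list test gave adjusted p = 1.09e-06, or adjusted p = 0.271 with an estimated correlation. Me1, malic enzyme, fell by 2.44 ± 0.24 (adjusted p = 1.64e-05) and Acss2, acetyl-CoA synthetase, fell by 3.545 ± 0.44 (adjusted p = 9.09e-05). In the other direction, Scd2, a desaturase of other tissues, rose by 1.68 ± 0.25 (adjusted p = 0.000289). Among genes of cholesterol synthesis and uptake, 23 of 25 fell (23 adjusted over the list alone), adjusted p = 4.27e-09, or adjusted p = 0.276 with an estimated correlation. They included Insig1, which restrains sterol regulatory proteins (-2.46 ± 0.26, adjusted p = 2.67e-05), and the sterol reductase gene Tm7sf2 (-3.01 ± 0.35, adjusted p = 5.87e-05). Among genes of bile acid synthesis and transport, 18 fell and 1 rose of 22 (18 fell and 1 rose adjusted over the list alone), adjusted p = 2.26e-06, or adjusted p = 0.276 with an estimated correlation. Nr0b2, the bile acid-responsive repressor, fell by 2.235 ± 0.24 (adjusted p = 3.31e-05), Cyp7b1 of the acidic pathway fell by 4.70 ± 0.65 (adjusted p = 0.000182), and the exporter Abcc4 rose by 1.95 ± 0.32 (adjusted p = 0.000508).

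Of the genes of methionine, choline and one-carbon metabolism, the pathway that the diet starves, 21 fell and 1 rose of 31 (23 fell and 1 rose adjusted over the list alone), adjusted p = 7.02e-07, or adjusted p = 0.271 with an estimated correlation. Gnmt, which consumes S-adenosylmethionine, fell by 2.69 ± 0.26 (adjusted p = 1.68e-05), Cbs fell by 1.56 ± 0.20 (adjusted p = 0.000104), and Mat2a, which makes S-adenosylmethionine outside the adult hepatocyte, rose by 0.66 ± 0.17 (adjusted p = 0.00790). Of the hepatocyte markers, 26 of 30 fell (27 adjusted over the list alone), adjusted p = 5.61e-10, or adjusted p = 0.276 with an estimated correlation. Examples included Serpinc1, antithrombin (-1.48 ± 0.24, adjusted p = 0.000553). Albumin took 7.96% ± 1.08 of the counts in the normal, 5.32% ± 1.06 in the model and 8.31% ± 0.781 in the TA group (SD, n = 3). Of the pericentral and xenobiotic enzymes, 16 fell and 3 rose of 30 (16 fell and 3 rose adjusted over the list alone), adjusted p = 0.000225, or adjusted p = 0.358 with an estimated correlation. These included Ces2a, a carboxylesterase, at -4.59 ± 0.32 (adjusted p = 2.12e-06) and Cyp2c29 at -4.56 ± 0.32 (adjusted p = 2.12e-06). Of the nuclear genes for oxidative phosphorylation, 24 of 33 fell (28 adjusted over the list alone), adjusted p = 2.16e-08, or adjusted p = 0.276 with an estimated correlation. They included Sdhd (-1.16 ± 0.17, adjusted p = 0.000222). The median of that list was -0.78, or -0.11 with library totals, where Ndufb8 and Cox5a lost their calls (adjusted p = 0.0988 and 0.318, over ranges of 4.09e-09 to 0.0988 and 5.06e-08 to 0.318). Of the acute phase and complement genes, 15 fell and 3 rose of 30 (16 fell and 3 rose adjusted over the list alone), adjusted p = 0.00447, or adjusted p = 0.543 with an estimated correlation. Examples included Crp at -1.75 ± 0.26 (adjusted p = 0.000293) and, in the other direction, Lcn2, lipocalin 2, at 4.03 ± 0.71 (adjusted p = 0.000857).

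Many macrophage transcripts rose. Of the macrophage and monocyte markers, 28 of 28 rose (28 adjusted over the list alone), adjusted p = 1.11e-15, or adjusted p = 0.271 with an estimated correlation. These included Cd68 (3.39 ± 0.16, adjusted p = 4.07e-07), Ctss (3.47 ± 0.22, adjusted p = 1.34e-06) and Itgax, which encodes CD11c (5.315 ± 0.37, adjusted p = 2.13e-06). Of the markers of lipid-associated macrophages, 18 of 22 rose (18 adjusted over the list alone), adjusted p = 5.61e-10, or adjusted p = 0.271 with an estimated correlation. They included Lgals3, galectin 3, at 5.22 ± 0.22 (adjusted p = 3.30e-07) and Capg at 4.82 ± 0.29 (adjusted p = 1.19e-06). Of the Kupffer cell markers, 10 rose and 2 fell of 17 (10 rose and 2 fell adjusted over the list alone), adjusted p = 0.0365, or adjusted p = 0.543 with an estimated correlation. Cd5l stood at 2.23 ± 0.39 (adjusted p = 0.000767) and Timd4 at -1.98, a call lost in several fits (range 0.000774 to 0.107). The Kupffer list lost its call with library totals (adjusted p = 0.287) or without normal replicate 2 (0.0559), model replicate 1 (0.0573) or model replicate 2 (0.0528), over a range of 0.0136 to 0.543. Neutrophil markers (13 of 14 rose, 14 adjusted over the list alone) and T cell and NK cell markers (20 of 25 rose, 21 adjusted over the list alone) were also higher. The tests gave adjusted p = 2.14e-05 and 1.05e-06 in turn, or 0.276 and 0.271 with an estimated correlation. Examples were Clec4d (5.18 ± 0.41, adjusted p = 4.43e-06) and Cd8a (2.95 ± 0.37, adjusted p = 9.62e-05).

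Inflammatory cytokines, chemokines and NF-kB targets followed, as 28 of 32 rose (28 rose and 1 fell adjusted over the list alone), adjusted p = 6.27e-11, or adjusted p = 0.0863 with an estimated correlation. Il1rn, the interleukin 1 receptor antagonist, rose by 4.415 ± 0.35 (adjusted p = 4.26e-06), the NF-kB inhibitor gene Tnfaip3 by 2.99 ± 0.26 (adjusted p = 8.69e-06) and Tlr2 by 2.56 ± 0.18 (adjusted p = 2.47e-06). Of the interferon-stimulated genes, 14 rose and 2 fell of 29 (14 rose and 2 fell adjusted over the list alone), adjusted p = 0.00456, or adjusted p = 0.543 with an estimated correlation. These included Oas3 at 2.89 ± 0.27 (adjusted p = 1.25e-05). Of the stellate cell and extracellular matrix genes, 37 rose and 1 fell of 42 (37 rose and 1 fell adjusted over the list alone), adjusted p = 1.11e-08, or adjusted p = 0.358 with an estimated correlation. They included Tgfb1, the main fibrogenic cytokine, at 2.23 ± 0.16 (adjusted p = 2.12e-06). Of the cholangiocyte and ductular reaction markers, 17 rose and 1 fell of 23 (18 rose and 1 fell adjusted over the list alone), adjusted p = 0.00456, or adjusted p = 0.539 with an estimated correlation. Examples included Spp1, osteopontin, at 3.32 ± 0.54 (adjusted p = 0.000564), but this list lost its call with library totals (adjusted p = 0.305, range 8.41e-06 to 0.539). Model replicate 2 stood apart for several of these markers, with Spp1 at 439, 96.2 and 389 CPM and Cd24a at 49.8, 8.42 and 51.6 CPM in model replicates 1 to 3. Of the liver endothelial markers, 11 of 27 rose (10 adjusted over the list alone), adjusted p = 0.00541, or adjusted p = 0.543 with an estimated correlation. These included Lyve1 at 3.54 ± 0.47 (adjusted p = 0.000138).

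Of the cell cycle genes, 27 of 33 rose (27 adjusted over the list alone), adjusted p = 4.27e-09, or adjusted p = 0.271 with an estimated correlation. Cyclin D1, Ccnd1, rose by 2.28 ± 0.21 (adjusted p = 1.21e-05) and Mki67, the marker of dividing cells, by 3.41 ± 0.37 (adjusted p = 3.21e-05). Of the apoptosis, p53 and ferroptosis genes, 19 rose and 3 fell of 31 (19 rose and 4 fell adjusted over the list alone), adjusted p = 0.00231, or adjusted p = 0.271 with an estimated correlation. They included Mlkl, the effector of necroptosis, at 1.74 ± 0.18 (adjusted p = 2.25e-05). Among male-biased liver genes 25 of 25 fell (25 adjusted over the list alone), adjusted p = 3.04e-12, or adjusted p = 0.271 with an estimated correlation. Among female-biased ones 13 rose and 3 fell of 18 (14 rose and 3 fell adjusted over the list alone), adjusted p = 0.00954, or adjusted p = 0.276 with an estimated correlation. The female-biased median was 3.02, or 2.52 with the 4 genes at 0 in a group set to their bound, and that list lost its call with library totals (adjusted p = 0.518, range 0.00167 to 0.518). Examples were Ugt2b1 (-2.93 ± 0.28, adjusted p = 1.38e-05) on the male side and Atp6v0d2 (4.165 ± 0.31, adjusted p = 2.77e-06), also a macrophage gene, on the female side.

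The 9 lists that were not called in this comparison held genes that went both ways. Among genes of fatty acid uptake and lipid droplets, 8 rose and 7 fell of 24 (8 rose and 8 fell adjusted over the list alone), adjusted p = 0.842, and the median of -0.08 became 0.59 with library totals. Lpl, lipoprotein lipase, rose by 3.65 ± 0.23 (adjusted p = 1.19e-06) and Cd36, a fatty acid transporter, by 3.39 ± 0.25 (adjusted p = 2.66e-06). The transporter gene Slc27a5 fell by 2.36 ± 0.29 (adjusted p = 8.74e-05). Among fatty acid oxidation genes and PPAR alpha targets, 8 rose and 8 fell of 32 (9 fell and 8 rose adjusted over the list alone), adjusted p = 0.755, with a median of -0.07, or 0.60 with library totals. Ucp2 rose by 2.87 ± 0.23 (adjusted p = 5.06e-06) and Fgf21, a stress hormone of liver, by 4.001 ± 0.53 (adjusted p = 0.000130). Of the NRF2 and glutathione genes 12 rose and 8 fell of 30 (12 rose and 9 fell adjusted over the list alone), adjusted p = 0.755. Called members included Slc7a11, the cystine transporter (6.45 ± 0.46, adjusted p = 2.22e-06), and Gstp1 (-2.68 ± 0.26, adjusted p = 1.68e-05). Of the unfolded protein and integrated stress response genes 10 fell and 6 rose of 32 (12 fell and 6 rose adjusted over the list alone), adjusted p = 0.434. Of the genes of gluconeogenesis, glycolysis and insulin response 16 fell and 7 rose of 33 (17 fell and 7 rose adjusted over the list alone), adjusted p = 0.0933. There the hexokinase gene Hk3 (2.93 ± 0.18, adjusted p = 1.22e-06) and Pkm (2.92 ± 0.20, adjusted p = 1.79e-06) rose. Of the immediate early genes 9 rose and 4 fell of 23 (9 rose and 4 fell adjusted over the list alone), adjusted p = 0.0959 and of the circadian clock genes 11 rose and 9 fell of 23 (13 rose and 9 fell adjusted over the list alone), adjusted p = 0.636. Of the B cell and plasma cell markers 2 rose and 1 fell of 12 (2 rose and 1 fell adjusted over the list alone), adjusted p = 0.512, and of the markers of adipose, muscle, pancreas, gut and red cells 4 fell and 1 rose of 9 (4 fell and 1 rose adjusted over the list alone), adjusted p = 0.0586. The last list is called the mixed-tissue list below. The medians of the NRF2, stress response, gluconeogenesis and mixed-tissue lists changed sign with library totals. That scaling gave calls to the gluconeogenesis list (adjusted p = 0.00789, range 0.00789 to 0.276) and the mixed-tissue list (0.00205, range 0.00205 to 0.271). The mixed-tissue list was also called in each fit without normal replicate 1 or 3, model replicate 1 or 3, or any TA replicate. Its medians there lay between -1.132 and -0.689. The immediate early list was called without normal replicate 3 (0.0369) or model replicate 2 (0.0288, range 0.00309 to 0.706).

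In all, 22 of 31 lists were called with the preset correlation, 13 higher and 9 lower. With the estimated correlation camera called 0 at the adjusted threshold and 4 at an unadjusted p under 0.05, while fry called 25.

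**Figure D2:**
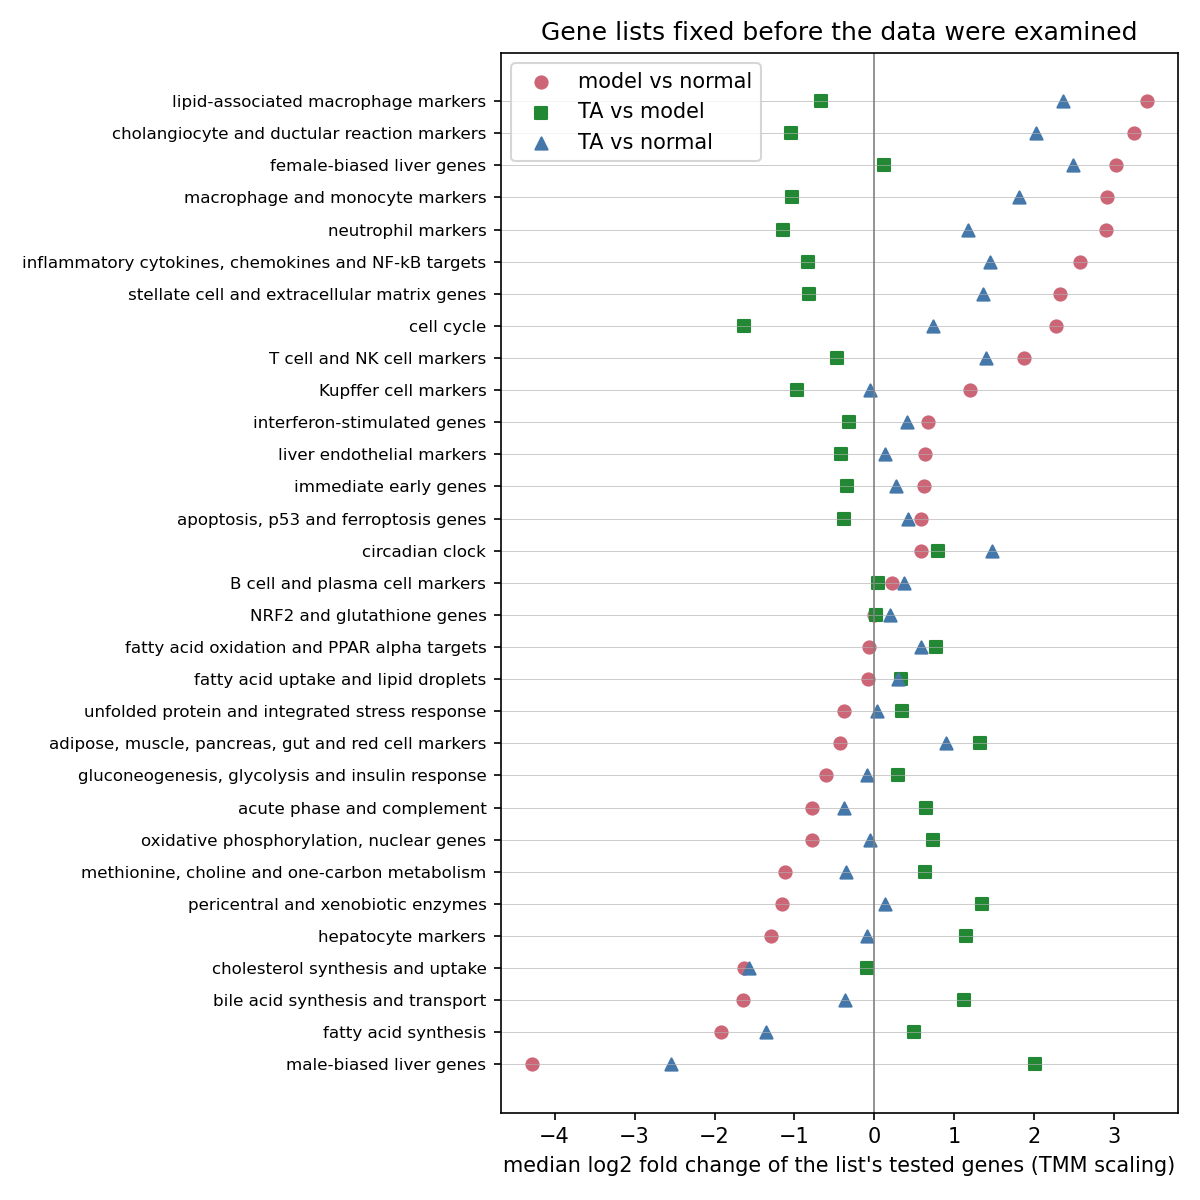
Median log2 fold change of the tested genes of each of the 31 gene lists fixed before the data were examined, for model against normal (circles), TA against model (squares) and TA against normal (triangles), with TMM scaling. The macrophage markers stand at 2.91, -1.03 and 1.81, the male-biased liver genes at -4.29, 2.01 and -2.54; with library totals the signs of 7 list medians flip in TA against model, among them those of fatty acid synthesis and female-biased genes, and 6 flip in model against normal.

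TA against model compared livers of mice on the diet with and without tormentic acid. Hepatocyte, oxidative phosphorylation and bile acid genes were higher in the TA group, and cell cycle, macrophage and inflammatory genes were lower. The tests of these lists were called with the preset correlation and gave adjusted p = 0.227 to 0.378 with an estimated correlation, and the oxidative phosphorylation median of 0.74 became 0.15 with library totals. Inmt, indolethylamine N-methyltransferase (ENSMUSG00000003477, chromosome 6, 55170626 to 55175043 on GRCm38), rose from 27.2 ± 8.14 to 389.5 ± 202 CPM (mean ± SD), by 3.84 ± 0.39 on the log2 scale (adjusted p = 0.00133). Mki67 (ENSMUSG00000031004, chromosome 7, 135689784 to 135716361 on GRCm38) fell from 35.9 ± 7.48 to 9.58 ± 3.73 CPM, a log2 fold change of -1.90 ± 0.33 (adjusted p = 0.00408). Of 13200 genes, 3031 changed, 1562 higher and 1469 lower. The authors' deposited table called 1817 genes, and 1750 of these were also called here in the same direction. With library totals alone 6122 genes were called and 6.55% of them were higher, against 51.5% with TMM factors. The count was 1444 without model replicate 1, 1436 without model replicate 3 and 1651 without TA replicate 3.

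Other large rises were in Clec2h, a C-type lectin gene (3.95 ± 0.46, adjusted p = 0.00163), Upp2, a uridine phosphorylase gene (3.34 ± 0.47, adjusted p = 0.00199), Cyp2c54 (3.66 ± 0.74, adjusted p = 0.00680) and the carboxylesterase gene Ces3b (3.12 ± 0.70, adjusted p = 0.0103). Cyp2c54 and Ces3b stood at 5.54 and 4.79 without model replicate 2. Mup7 rose by 5.09 ± 1.21 (adjusted p = 0.0135), Mup19 by 4.915 ± 1.17 (adjusted p = 0.0135) and Thrsp, a lipogenic regulator, by 3.07 ± 0.83 (adjusted p = 0.0223). Without model replicate 1 these 3 gave adjusted p = 0.0533, 0.0575 and 0.0870. Mup19 also lost its call without model replicate 3 (adjusted p = 0.0561) and with limma-voom (0.113). Without TA replicate 1, Mup7 and Mup19 stood at 3.58 and 2.81, and without model replicate 2 at 7.36 and 6.75. Thrsp lost its call without model replicate 3 (adjusted p = 0.0567) or TA replicate 3 (0.0821), and stood at 4.85 without model replicate 2. Over all alternatives the adjusted p ran from 0.000697 to 0.0533 for Mup7, from 0.00225 to 0.113 for Mup19 and from 0.000392 to 0.0870 for Thrsp.

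The largest falls were in Inhbb, an activin subunit gene (-3.20 ± 0.40, adjusted p = 0.00163), Cntnap1 (-3.05 ± 0.28, adjusted p = 0.00131), Fam83a (-2.965 ± 0.51, adjusted p = 0.00374) and Pcdh17, a protocadherin gene (-2.68 ± 0.40, adjusted p = 0.00243). Psat1, of serine synthesis (-2.46 ± 0.46, adjusted p = 0.00531), Rims3 (-2.39 ± 0.40, adjusted p = 0.00371), and Mybl1, a MYB-family transcription factor gene (-2.35 ± 0.26, adjusted p = 0.00156), fell too. Cyp2a4 fell by 2.62 ± 0.60 (adjusted p = 0.0110), with adjusted p = 0.0511 without TA replicate 3 and a range of 0.00254 to 0.0511. It stood at -1.88 without model replicate 1 and -3.53 without TA replicate 2, and Psat1 stood at -3.32 without TA replicate 1.

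Many hepatocyte genes rose. Of the hepatocyte markers, 23 of 30 rose (26 adjusted over the list alone), adjusted p = 2.06e-13, or adjusted p = 0.319 with an estimated correlation. Examples included Tdo2, tryptophan dioxygenase (1.63 ± 0.27, adjusted p = 0.00356). Of the nuclear genes for oxidative phosphorylation, 28 of 33 rose (31 adjusted over the list alone), adjusted p = 7.16e-12, or adjusted p = 0.319 with an estimated correlation. These included Ndufa9 at 0.80 ± 0.16 (adjusted p = 0.00611) and Ndufv1 at 0.78 ± 0.15 (adjusted p = 0.00611). The median of that list was 0.74, or 0.15 with library totals, where Ndufa9 and Ndufv1 lost their calls (adjusted p = 0.177 and 0.235, over ranges of 5.35e-05 to 0.177 and 9.45e-06 to 0.235). Mitochondrial transcripts also took a larger share of the counts in TA replicates 2 and 3 (12.5% and 15.4%) than in the model libraries (7.36% to 11.6%), but a smaller one in TA replicate 1 (4.92%). Of the pericentral and xenobiotic enzymes, 18 rose and 1 fell of 30 (21 rose and 1 fell adjusted over the list alone), adjusted p = 9.11e-10, or adjusted p = 0.319 with an estimated correlation. They included Ces2a (2.85 ± 0.30, adjusted p = 0.00142), Ugt1a1, which conjugates bilirubin (1.52 ± 0.18, adjusted p = 0.00163), and Cyp2c29 (2.11 ± 0.29, adjusted p = 0.00193). Of the male-biased genes, 13 of 25 rose (17 adjusted over the list alone), adjusted p = 3.31e-07, or adjusted p = 0.406 with an estimated correlation. Examples included Ugt2b1 (1.43 ± 0.26, adjusted p = 0.00498) and Mup3 (3.05 ± 0.63, adjusted p = 0.00762). TA replicate 1 stood apart for several members, such as Mup7 at 356.5, 73.25 and 35.1 CPM and Hsd3b5 at 15.3, 1.96 and 0.261 CPM in TA replicates 1 to 3. The median of the list was 2.01, or 1.68 with the 1 gene at 0 set to its bound.

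Of the genes of bile acid synthesis and transport, 14 rose and 1 fell of 22 (17 rose and 2 fell adjusted over the list alone), adjusted p = 6.20e-07, or adjusted p = 0.378 with an estimated correlation. The sterol exporter genes Abcg5 and Abcg8 rose by 1.64 ± 0.25 (adjusted p = 0.00273) and 1.70 ± 0.27 (adjusted p = 0.00295), and Nr0b2 by 1.49 ± 0.24 (adjusted p = 0.00300). Of the methionine, choline and one-carbon genes, 14 rose and 1 fell of 31 (14 rose and 2 fell adjusted over the list alone), adjusted p = 4.80e-05, or adjusted p = 0.382 with an estimated correlation. These included Gnmt at 1.76 ± 0.25 (adjusted p = 0.00216) and Ahcy at 1.69 ± 0.28 (adjusted p = 0.00364). Of the fatty acid oxidation genes and PPAR alpha targets, 15 rose and 3 fell of 32 (21 rose and 4 fell adjusted over the list alone), adjusted p = 2.38e-05, or adjusted p = 0.415 with an estimated correlation. They included Acaa2, a thiolase, at 1.05 ± 0.21 (adjusted p = 0.00683) and Fgf21 at -2.32 ± 0.47 (adjusted p = 0.00700). Of the fatty acid synthesis genes, 4 rose and 1 fell of 20 (4 rose and 1 fell adjusted over the list alone), adjusted p = 0.00937, or adjusted p = 0.478 with an estimated correlation, and their median of 0.49 became -0.08 with library totals. Scd1 rose by 2.89 ± 0.51 (adjusted p = 0.00435) and Mlxipl, a glucose-responsive lipogenic factor, by 1.59 ± 0.22 (adjusted p = 0.00199). Of the acute phase and complement genes, 7 of 30 rose (7 adjusted over the list alone), adjusted p = 0.00114, or adjusted p = 0.507 with an estimated correlation. Examples included Crp at 1.21 ± 0.26 (adjusted p = 0.00812). Of the circadian clock genes, 10 of 23 rose (12 adjusted over the list alone), adjusted p = 0.000367, or adjusted p = 0.319 with an estimated correlation. These included Cry2 (1.40 ± 0.18, adjusted p = 0.00176) and Nr1d1 (1.49 ± 0.25, adjusted p = 0.00372). Of the markers of adipose, muscle, pancreas, gut and red cells, 6 of 9 rose (7 rose and 1 fell adjusted over the list alone), adjusted p = 0.00149, or adjusted p = 0.227 with an estimated correlation. Those that rose included the red cell genes Alas2 (1.43 ± 0.31, adjusted p = 0.00948) and Hba-a1 (1.35 ± 0.29, adjusted p = 0.00901).

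Many cell cycle genes fell, as 26 of 33 fell (28 adjusted over the list alone), adjusted p = 8.33e-11, or adjusted p = 0.295 with an estimated correlation. They included Mcm2 (-1.66 ± 0.25, adjusted p = 0.00258) and Top2a (-2.06 ± 0.35, adjusted p = 0.00372). Of the macrophage and monocyte markers, 21 of 28 fell (25 adjusted over the list alone), adjusted p = 1.69e-10, or adjusted p = 0.319 with an estimated correlation. Examples included Csf1r, the receptor that sustains macrophages, at -1.33 ± 0.19 (adjusted p = 0.00218), Cd68 at -0.97 ± 0.14 (adjusted p = 0.00234) and Adgre1, which encodes F4/80, at -1.935 ± 0.30 (adjusted p = 0.00291). Of the lipid-associated macrophage markers, 11 of 22 fell (15 fell and 1 rose adjusted over the list alone), adjusted p = 7.00e-05, or adjusted p = 0.382 with an estimated correlation. These included Mmp12 at -1.265 ± 0.28 (adjusted p = 0.00937) and Anxa2 at -1.47 ± 0.22 (adjusted p = 0.00232). Of the inflammatory genes, 19 of 32 fell (19 adjusted over the list alone), adjusted p = 1.59e-07, or adjusted p = 0.227 with an estimated correlation. They included Csf1 at -0.98 ± 0.15 (adjusted p = 0.00291), the endotoxin receptor gene Tlr4 at -1.87 ± 0.34 (adjusted p = 0.00467) and Vcam1 at -1.91 ± 0.39 (adjusted p = 0.00723). Of the stellate cell and matrix genes, 10 of 42 fell (10 adjusted over the list alone), adjusted p = 4.80e-05, or adjusted p = 0.506 with an estimated correlation. Examples included Tgfb1 (-1.003 ± 0.15, adjusted p = 0.00233). Of the liver endothelial markers, 8 of 27 fell (9 adjusted over the list alone), adjusted p = 0.000545, or adjusted p = 0.498 with an estimated correlation. These included Lyve1 (-1.96 ± 0.43, adjusted p = 0.00940).

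Kupffer cell, neutrophil, T cell and NK cell, interferon and apoptosis lists were also called lower with the preset correlation, though no T cell or NK cell marker passed on its own. Of the Kupffer cell markers, 8 of 17 fell (9 adjusted over the list alone), adjusted p = 0.00114, or adjusted p = 0.430 with an estimated correlation. They included Cd5l (-1.79 ± 0.38, adjusted p = 0.00821). Of the neutrophil markers, 7 of 14 fell (8 adjusted over the list alone), adjusted p = 0.00114, or adjusted p = 0.415 with an estimated correlation. Of the T cell and NK cell markers 0 of 25 changed (0 adjusted over the list alone), adjusted p = 0.0106, or adjusted p = 0.430 with an estimated correlation. Of the interferon-stimulated genes, 5 of 29 fell (5 adjusted over the list alone), adjusted p = 0.0187, or adjusted p = 0.591 with an estimated correlation. Examples included Zbp1 (-0.85 ± 0.20, adjusted p = 0.0116). Of the apoptosis, p53 and ferroptosis genes, 8 fell and 1 rose of 31 (9 fell and 1 rose adjusted over the list alone), adjusted p = 0.0325, or adjusted p = 0.382 with an estimated correlation. These included Mlkl (-1.32 ± 0.17, adjusted p = 0.00183) and Acsl4 (-1.10 ± 0.14, adjusted p = 0.00181). Without TA replicate 1 the interferon (adjusted p = 0.293), Kupffer (0.0639), T cell (0.0543) and apoptosis (0.117) lists lost their calls, as did the interferon list without model replicate 2 (0.0941) and the apoptosis list without model replicate 3 (0.0505). Library totals ended the calls of the neutrophil (0.0622), T cell (0.162) and stellate cell (0.0659) lists. The lowest and highest adjusted p over the alternatives were 0.000887 and 0.610 for interferon, 9.61e-06 and 0.430 for Kupffer, 0.00113 and 0.430 for T cell, 0.0129 and 0.382 for apoptosis, 7.78e-05 and 0.415 for neutrophil and 1.16e-09 and 0.506 for stellate cell genes.

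Not called were the lists of fatty acid uptake and lipid droplets (6 rose and 5 fell of 24, 8 rose and 5 fell adjusted over the list alone), cholesterol synthesis (4 of 25 rose, 2 adjusted over the list alone), NRF2 and glutathione (7 fell and 6 rose of 30, 7 rose and 7 fell adjusted over the list alone), unfolded protein response (5 rose and 4 fell of 32, 13 rose and 4 fell adjusted over the list alone), B cells (0 of 12 changed, 0 adjusted over the list alone), cholangiocytes (1 of 23 rose, 1 adjusted over the list alone), female-biased genes (3 fell and 1 rose of 18, 4 fell and 1 rose adjusted over the list alone), gluconeogenesis (7 rose and 4 fell of 33, 9 rose and 4 fell adjusted over the list alone) and immediate early genes (6 fell and 2 rose of 23, 8 fell and 2 rose adjusted over the list alone). Their adjusted p ran from 0.0695 to 0.976, and the medians of the lipid droplet, NRF2, unfolded protein, B cell, female-biased and gluconeogenesis lists changed sign with library totals. That scaling gave calls to the lipid droplet (adjusted p = 0.00232, range 0.00232 to 0.478), unfolded protein (0.00594, range 0.00594 to 0.610) and gluconeogenesis lists (0.0341, range 0.0341 to 0.382). Without model replicate 2 the lists of cholangiocytes (0.000246, range 3.07e-06 to 0.697), cholesterol synthesis (0.00903, range 0.00903 to 0.999) and immediate early genes (0.0280, range 0.0280 to 0.946) were called, as was the cholangiocyte list without TA replicate 1 (0.0127). The unfolded protein list was called without model replicate 3 (0.00821), TA replicate 2 (0.0481) or TA replicate 3 (0.0306), and the lipid droplet list without model replicate 1 (0.0363) or TA replicate 2 (0.0481). In these lists Hmox1, haem oxygenase (-1.61 ± 0.22, adjusted p = 0.00190), Cidec, a lipid droplet gene (-1.95 ± 0.30, adjusted p = 0.00289), and Atf3, a stress-induced transcription factor gene (-1.24 ± 0.19, adjusted p = 0.00265), fell. Pck1, the rate-limiting gene of gluconeogenesis (1.425 ± 0.28, adjusted p = 0.00622), and Herpud1 (1.21 ± 0.23, adjusted p = 0.00534) rose. With the estimated correlation camera called 0 lists at the adjusted threshold and 3 at an unadjusted p under 0.05, and fry called 13, against 22 with the preset correlation (11 higher and 11 lower).

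Many genes moved in opposite directions in these comparisons. Of the 6344 genes called in model against normal, 2620 changed the other way in TA against model, 1310 that were higher in the model group and 1310 that were lower. Independent lists of these sizes would share 727 genes in opposite and 730 in the same direction, but both comparisons hold the model libraries with opposite signs. In 50 simulated data sets with no effect, that sharing gave a covariance of the fold changes of -0.0611 (-0.0684 to -0.0546) against -0.844 in the data. The 3 model libraries could not be divided into separate sets of at least 2 for each comparison, so part of the excess may still rest on them. The count was 1263 without model replicate 1, 1314 without model replicate 3, 1527 without TA replicate 3 and 5274 with library totals alone.

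Among the genes with the largest opposite changes, Inmt fell by 4.06 ± 0.39 in model against normal and rose by 3.84 ± 0.39 in TA against model (adjusted p = 1.68e-05 and adjusted p = 0.00133 in turn), and Cyp2c54 fell by 3.62 ± 0.74 and rose by 3.66 ± 0.74 (adjusted p = 0.00203 and adjusted p = 0.00680). The change of Cyp2c54 was -5.505 and 5.543 without model replicate 2. Hsd3b5 rose by 5.51 ± 1.20 in TA against model (adjusted p = 0.00919), or by 3.08 without TA replicate 1. In limma-voom it gave adjusted p = 0.105, over a range of 0.00306 to 0.105. Mup7, Mup19, Mup12 and Mup15 rose by between 4.52 and 5.09, and Esm1, an endothelial gene, fell by 3.97 ± 1.09 (adjusted p = 0.0240) after a rise of 4.02 ± 1.09 (adjusted p = 0.0105, or 0.219 with limma-voom, over a range of 6.96e-05 to 0.219). Calls of Mup7, Mup19, Mup12, Mup15 and Esm1 in TA against model were lost without model replicate 1 (adjusted p = 0.0533, 0.0575, 0.0855, 0.115 and 0.0985). All of these but Mup7 were also lost without model replicate 3 (0.0561, 0.0772, 0.116 and 0.0566). Without TA replicate 1, Mup12, Mup15 and Esm1 were not called (0.0900, 0.266 and 0.0626), and Mup15 and Mup19 stood at 2.16 and 2.81. Mup15 was not called without model replicate 2 (0.0558), where Mup12 stood at 7.53, and Esm1 was not called without TA replicate 3 (0.0878). Over the alternatives their highest adjusted p was 0.0533, 0.113, 0.182, 0.371 and 0.268 in turn, and the lowest 0.000697, 0.00225, 0.00924, 0.0141 and 0.00118.

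Only 13 genes changed in the same direction in both, 11 higher and 2 lower. The count was 8 without normal replicate 1, normal replicate 2 or model replicate 1, 3 without model replicate 3, 24 without TA replicate 1, 6 without TA replicate 2 and 4 without TA replicate 3. The 4 with the largest changes were 3 clock-controlled genes, Dbp (5.43 ± 0.97 and 2.19 ± 0.67), Ciart (3.34 ± 0.91 and 2.52 ± 0.67) and Usp2 (1.70 ± 0.46 and 2.23 ± 0.43), and Igfbp2, an insulin-like growth factor binding protein gene (0.99 ± 0.30 and 0.93 ± 0.30). Their adjusted p for TA against model were 0.0368, 0.0216, 0.0057 and 0.0461. Calls of Dbp, Ciart and Igfbp2 there were lost without model replicate 3 (0.0663, 0.0682 and 0.170), TA replicate 2 (0.0815, 0.0740 and 0.0958) or TA replicate 3 (0.102, 0.0656 and 0.0954). Dbp was also lost without normal replicate 2 (0.0525) or model replicate 2 (0.0769), and stood at 3.74 without model replicate 1. Igfbp2 was also lost without normal replicate 2 (0.0650), normal replicate 3 (0.0501), model replicate 1 (0.10) or TA replicate 1 (0.0763). Dbp and Igfbp2 also lost those calls with library totals (0.0779 and 0.273), and Dbp with DESeq2 (0.0593). In model against normal, limma-voom ended the calls of Dbp (0.0795), Ciart (0.201) and Usp2 (0.0702). Without model replicate 1, Usp2 stood at 1.115 with adjusted p = 0.0514 and Ciart at 2.188, and Igfbp2 had adjusted p = 0.0725 without normal replicate 1. The lowest and highest adjusted p over the alternatives for TA against model were 0.00893 and 0.102 for Dbp, 0.00589 and 0.0740 for Ciart and 0.00811 and 0.273 for Igfbp2, and for model against normal 9.90e-08 and 0.0795 for Dbp, 0.00133 and 0.201 for Ciart, 0.000435 and 0.0702 for Usp2 and 0.000648 and 0.0725 for Igfbp2.

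**Figure D3:**
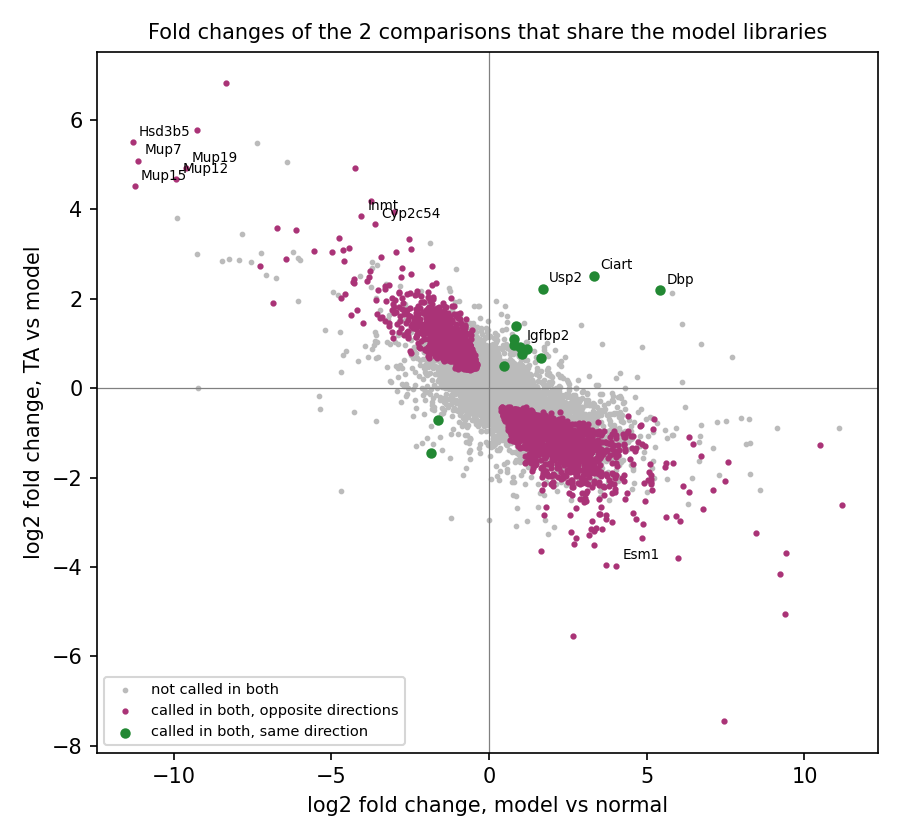
Fitted log2 fold change of each tested gene in model against normal (horizontal) and in TA against model (vertical), with 2620 genes called in opposite directions in purple, 13 called in the same direction in green and all others in grey. Most called genes lie in the upper left and lower right, where sharing the model libraries alone also places genes; fitted values of genes with few counts are not bounds.

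TA against normal, a secondary comparison, asked how far the treated livers still lay from normal ones. Macrophage genes and 22 of 42 matrix genes were higher than normal and fatty acid and cholesterol synthesis genes lower, while hepatocyte markers showed no called change. The tests of these lists, called with the preset correlation except for hepatocytes, gave adjusted p = 0.231 to 0.805 with an estimated correlation. Mmp12 stood at 176 ± 25.7 CPM against 0.289 ± 0.251, 9.23 ± 0.45 on the log2 scale (adjusted p = 1.18e-06). Cyp2a4 had a ratio of 464 (95% counting interval 82.9 to 18370) and stood at 3.75, 24.8 and 10.09 CPM in TA replicates 1 to 3. Dbp rose by 7.625 ± 0.98 (adjusted p = 0.000561) and Cyp2b9 by 7.54 ± 1.28 (adjusted p = 0.00250). Mup15 fell by 6.72 ± 1.24 (adjusted p = 0.00418), Mup17 fell by 6.07 ± 1.40 (adjusted p = 0.0133), Mup7 fell by 6.04 ± 1.25 (adjusted p = 0.00771) and Pitx3 fell by 6.27 ± 0.74 (adjusted p = 0.000312). Without TA replicate 1, Mup15, Mup17 and Mup7 stood at -9.097, -8.549 and -7.58. Pitx3 had counts in TA replicate 1 (1.09 CPM) and 0 in the other TA libraries, and these may be Elovl3 reads as above. Cyp2b9, with 0 counts in the normal group without replicate 1, stood at 6.945 without normal replicate 3 and 6.59 without TA replicate 3, Mmp12 at 8.63 and Dbp at 8.38 without normal replicate 3, and Mup17 at -5.35 without normal replicate 2. Cyp2a4 and Cyp2b9 lost their calls with limma-voom (adjusted p = 0.0687 and 0.283, over ranges of 1.00e-07 to 0.0687 and 2.64e-05 to 0.283).

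Of 13200 genes, 2081 differed between TA and normal livers, 1417 higher and 664 lower. The count was 1332 without normal replicate 1 and 1092 without normal replicate 3. Of the 6344 genes called in model against normal, 1875 (29.6%) were still called in the same direction and 4 in the other. Of the 2620 genes with opposite changes, 721 were still called in the model direction. A lost call is not a return to normal.

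Genes named from here on for TA against normal were chosen after their values were seen. Of the macrophage markers 26 of 28 rose (28 adjusted over the list alone), adjusted p = 2.41e-19, or adjusted p = 0.231 with an estimated correlation. They included Cd68 at 2.42 ± 0.15 (adjusted p = 8.27e-06). Of the lipid-associated macrophage markers 17 of 22 rose (18 rose and 1 fell adjusted over the list alone), adjusted p = 6.97e-13, or adjusted p = 0.231 with an estimated correlation. Examples included Gpnmb at 7.33 ± 0.38 (adjusted p = 1.70e-06). Of the inflammatory genes 17 of 32 rose (22 rose and 1 fell adjusted over the list alone), adjusted p = 5.26e-10, or adjusted p = 0.115 with an estimated correlation. Of the stellate cell and matrix genes 22 of 42 rose (28 adjusted over the list alone), adjusted p = 2.09e-07, or adjusted p = 0.557 with an estimated correlation. These included Col1a1, type I collagen, at 3.43 ± 0.63 (adjusted p = 0.00398). Of the neutrophil markers 6 of 14 rose (7 adjusted over the list alone), adjusted p = 0.00205, or adjusted p = 0.535 with an estimated correlation. Of the T cell and NK cell markers 9 of 25 rose (13 adjusted over the list alone), adjusted p = 5.50e-07, or adjusted p = 0.275 with an estimated correlation. Of the cholangiocyte markers 5 rose and 1 fell of 23 (11 rose and 1 fell adjusted over the list alone), adjusted p = 0.0101, or adjusted p = 0.675 with an estimated correlation. Of the cell cycle genes 6 of 33 rose (6 adjusted over the list alone), adjusted p = 0.0106, or adjusted p = 0.559 with an estimated correlation. Of the interferon-stimulated genes 8 of 29 rose (12 rose and 1 fell adjusted over the list alone), adjusted p = 0.0454, or adjusted p = 0.794 with an estimated correlation. Of the apoptosis, p53 and ferroptosis genes 12 rose and 2 fell of 31 (13 rose and 2 fell adjusted over the list alone), adjusted p = 0.0101, or adjusted p = 0.275 with an estimated correlation. The cholangiocyte list was not called without TA replicate 1 (adjusted p = 0.182, range 0.000339 to 0.675), nor the cell cycle list without normal replicate 1 (0.0780) or TA replicate 1 (0.0799, range 0.00129 to 0.559). The interferon list was not called without normal replicate 2 (0.253), normal replicate 3 (0.113), model replicate 2 (0.0686), TA replicate 2 (0.168) or TA replicate 3 (0.110), over a range of 0.00152 to 0.794.

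Many cholesterol and fatty acid synthesis genes were lower than in normal livers. Of the cholesterol synthesis genes, 21 of 25 fell (24 adjusted over the list alone), adjusted p = 1.30e-14, or adjusted p = 0.275 with an estimated correlation. They included Dhcr7, the last enzyme of the pathway (-2.265 ± 0.30, adjusted p = 0.000614). Of the fatty acid synthesis genes, 12 of 20 fell (15 adjusted over the list alone), adjusted p = 1.29e-08, or adjusted p = 0.275 with an estimated correlation. Examples included Scd1 (-3.54 ± 0.53, adjusted p = 0.00124) and Acacb (-2.585 ± 0.36, adjusted p = 0.000791). Of the bile acid genes 3 of 22 fell (5 adjusted over the list alone), adjusted p = 0.0124, or adjusted p = 0.675 with an estimated correlation. Of the methionine, choline and one-carbon genes 6 fell and 1 rose of 31 (9 fell and 1 rose adjusted over the list alone), adjusted p = 0.000194, or adjusted p = 0.410 with an estimated correlation. Of the male-biased genes 15 of 25 fell (23 adjusted over the list alone), adjusted p = 4.68e-14, or adjusted p = 0.275 with an estimated correlation. Of the female-biased ones 9 rose and 3 fell of 18 (12 rose and 3 fell adjusted over the list alone), adjusted p = 0.00395, or adjusted p = 0.275 with an estimated correlation. Their median was 2.49, or 2.21 with genes at 0 set to their bound. Of the fatty acid oxidation genes and PPAR alpha targets 12 of 32 rose (16 rose and 1 fell adjusted over the list alone), adjusted p = 0.000255, or adjusted p = 0.557 with an estimated correlation. They included Acot2 at 2.05 ± 0.27 (adjusted p = 0.000588).

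Lists without a call were those of hepatocytes (0 of 30 changed, 0 adjusted over the list alone), oxidative phosphorylation (0 of 33 changed, 0 adjusted over the list alone), lipid uptake and droplets (6 of 24 rose, 6 adjusted over the list alone), NRF2 (8 rose and 3 fell of 30, 9 rose and 3 fell adjusted over the list alone), unfolded protein response (4 of 32 rose, 3 adjusted over the list alone), acute phase (3 fell and 2 rose of 30, 4 fell and 3 rose adjusted over the list alone), Kupffer cells (1 of 17 rose, 1 adjusted over the list alone), B cells (1 rose and 1 fell of 12, 1 rose and 1 fell adjusted over the list alone), endothelium (2 of 27 rose, 0 adjusted over the list alone), pericentral enzymes (5 rose and 3 fell of 30, 6 rose and 4 fell adjusted over the list alone), gluconeogenesis (7 rose and 7 fell of 33, 7 rose and 7 fell adjusted over the list alone), immediate early genes (4 rose and 3 fell of 23, 4 rose and 3 fell adjusted over the list alone) and adipose, muscle, pancreas, gut and red cells (3 rose and 2 fell of 9, 4 rose and 2 fell adjusted over the list alone). Their adjusted p ran from 0.0544 to 0.943, and the medians of the hepatocyte, oxidative phosphorylation and Kupffer lists changed sign with library totals. Library totals gave a call to the acute phase list (adjusted p = 0.0313, range 0.00206 to 0.794). Without TA replicate 3 the lists of hepatocytes (0.0122, range 0.0122 to 0.805), oxidative phosphorylation (0.0256, range 0.0256 to 0.805) and acute phase genes (0.0422) were called lower, as were those of hepatocytes (0.0476) and acute phase genes (0.00206) without normal replicate 3. The endothelial list was called without TA replicate 1 (0.0120, range 0.0120 to 0.957), the Kupffer list without TA replicate 2 (0.0420, range 0.0420 to 0.993) and the lipid droplet list without normal replicate 2 (0.0230) or TA replicate 2 (0.0304, range 0.0144 to 0.557). Haemoglobin gene Hba-a1 stood at 1.24 ± 0.29 (adjusted p = 0.0149), with adjusted p = 0.0648 without normal replicate 1, 0.0683 without normal replicate 3 and 0.0545 without TA replicate 3, over a range of 0.000541 to 0.0683. With the estimated correlation camera called 0 lists at the adjusted threshold and 4 at an unadjusted p under 0.05, and fry called 13, against 18 with the preset correlation (13 higher and 5 lower).

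Clock genes also differed between TA and normal livers, where 15 rose and 5 fell of 23 (15 rose and 5 fell adjusted over the list alone), adjusted p = 0.00256, or adjusted p = 0.275 with an estimated correlation. Among genes chosen after their values were seen, the clock repressor gene Nr1d1 (ENSMUSG00000020889, chromosome 11, 98767932 to 98775333 on GRCm38) rose by 2.05 ± 0.26 (adjusted p = 0.000494), Wee1 by 2.94 ± 0.33 (adjusted p = 0.000228) and Bhlhe41 by 4.50 ± 0.50 (adjusted p = 0.000213), while Npas2, an activator of the clock, fell by 3.09 ± 0.43 (adjusted p = 0.000824). Within the model group Dbp stood at 54.5 CPM in replicate 1 against 11.7 and 4.51 in replicates 2 and 3, and in TA replicate 1 at 66.6 CPM against 124.7 and 132.9.

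**Figure D4:**
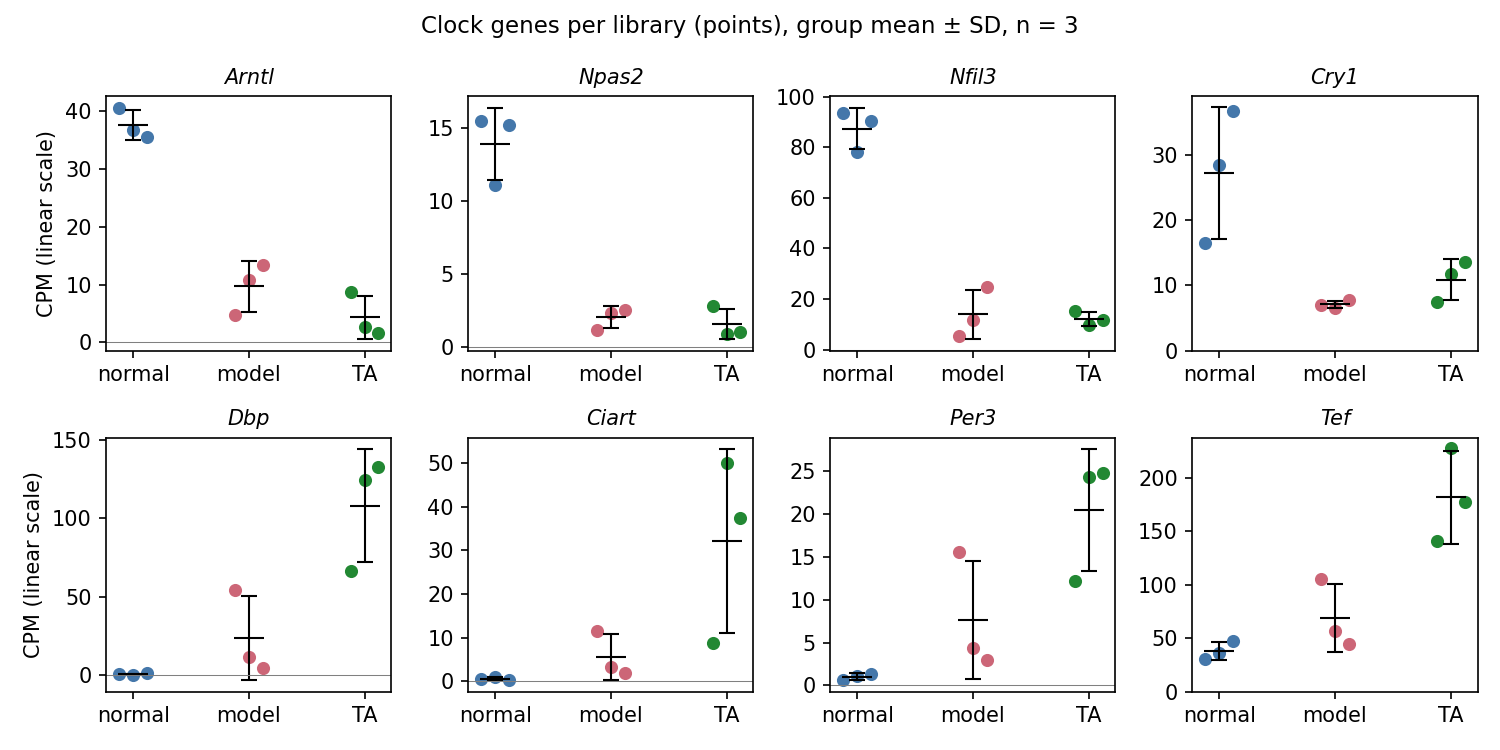
CPM on a linear scale of 8 clock genes in each library (points), with the group mean and SD (n = 3 per group), for normal, model and TA livers. Arntl, Npas2, Nfil3 and Cry1 are higher in the normal group, and Dbp, Ciart, Per3 and Tef are higher in the TA group.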

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

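All alternatives were planned before the data were examined, except the 1 that leaves out model replicate 2 and TA replicate 1, chosen after seeing the data. Library totals without factors raised the count for TA against model from 3031 to 6122 genes, 6.55% of them higher, and the count of opposite changes from 2620 to 5274, by construction, since the median gene then moved by -0.577. A minimum of 2-fold lowered the counts by construction, to 3825, 1440 and 1335 genes for model against normal, TA against model and TA against normal, and to 1258 opposite changes. Camera with an estimated correlation called 0, 0 and 0 lists in the 3 comparisons at the adjusted threshold, with 4, 3 and 4 at an unadjusted p under 0.05, and fry called 25, 13 and 13. With the preset correlation the counts were 22, 22 and 18. The estimated correlation allows for genes of a list that move together, which widens each list's error.

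Leaving out 1 library at a time gave 4830 to 6869 genes for model against normal, 1436 to 3793 for TA against model, 1092 to 2467 for TA against normal, 1263 to 3370 opposite changes and 3 to 24 changes of the same direction. The lower counts came without model replicate 3 (1436), model replicate 1 (1444) or TA replicate 3 (1651) for TA against model, without normal replicate 3 (1092) or 1 (1332) for TA against normal, and without model replicate 1 (1263), model replicate 3 (1314) or TA replicate 3 (1527) for opposite changes. The same-direction count of 13 was 3 without model replicate 3, 4 without TA replicate 3, 6 without TA replicate 2, 8 without model replicate 1, normal replicate 1 or normal replicate 2, and 24 without TA replicate 1. List counts ran from 21 to 24, 19 to 24 and 17 to 20. With both model replicate 2 and TA replicate 1 left out, the counts were 7214, 4306 and 2574 genes, 3730 opposite changes and 23, 20 and 18 lists. DESeq2 called 6622, 3622 and 2762 genes, limma-voom 6234, 3250 and 1538, and the replicate block 5711, 2294 and 1575.

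Of 453 values of named genes, 390 were called. Of these calls, 386 were kept with DESeq2 size factors, 363 with library totals, 389 without a filter, 370 with the replicate block and 364 with limma-voom. DESeq2 kept 380 of 382, and leaving out 1 library kept 354 to 385. Of 62 list calls, 47 were kept by fry, 56 with library totals and 56 to 61 with 1 library left out. Library totals gave calls to 6 lists that had none. Among named genes called with either scaling, 3 changed sign with library totals. They were Bst2 (0.000787) and Tyms (0.564) in model against normal and Aifm2 (-0.0687) in TA against model. Sign changes of named genes called with neither scaling were not counted. The alternatives for normalized values (another pseudocount, no filter on low values) were not run, since counts were at hand. DESeq2 gave no adjusted p for 7 genes in each comparison.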

Other observations

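The pathway tests and the 6 tests of explanations below were chosen only after the results were seen, while the splits of the libraries were planned before.

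Pathway terms gave a wider view of the genes called in each comparison. Among genes lower in the model group, the proteasome had 31 of 45 genes against 11.6 by chance (adjusted p = 3.40e-08, Fisher exact test) and the citrate cycle 22 of 29 against 7.45 (adjusted p = 3.57e-07). Branched-chain amino acid degradation had 33 of 47 genes lower in the model group (12.1 by chance, adjusted p = 4.92e-09) and 33 of 47 genes higher in TA against model (6.66 by chance, adjusted p = 3.44e-16). Oxidative phosphorylation had 59 of 106 genes lower in the model group (27.2 by chance, adjusted p = 1.32e-09) and 61 of 106 higher in TA against model (15.02 by chance, adjusted p = 2.15e-23). Fc gamma receptor phagocytosis had 32 of 74 genes lower in TA against model (9.68 by chance, adjusted p = 1.53e-08), and steroid biosynthesis 12 of 17 genes lower in TA against normal (0.95 by chance, adjusted p = 1.00e-09). Genes of a pathway are not independent, so these p-values overstate the evidence.

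Among the 202 genes called in TA against normal and not in model against normal, fatty acid degradation held 6 of 45 genes against 0.68 by chance (adjusted p = 0.0129, Fisher exact test). They were Acadl, Acadm, Acsl4, Aldh3a2, Cyp4a10 and Eci2. Acsl4, an acyl-CoA synthetase of ferroptosis, fell by 0.98 ± 0.14 against normal (adjusted p = 0.00119) and by 1.10 ± 0.14 against model (adjusted p = 0.00181). Cyp2a5, a coumarin hydroxylase gene of the P450 family that was chosen after its values were seen (ENSMUSG00000005547, chromosome 7, 26835305 to 26843548 on GRCm38), stood at 190.2 ± 24.8 CPM in normal, 224 ± 38.4 in model and 859 ± 369 in TA livers (mean ± SD, n = 3). It rose by 2.175 ± 0.29 against normal (adjusted p = 0.000689). That these genes changed only with TA was not tested, since a gene that misses the threshold in 1 comparison is not shown to differ from the other.

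The splits of the libraries asked how many calls other groupings gave. For each pair of groups the 6 libraries make 10 splits, too few for a share under 0.05. In model against normal 1 of 10 splits gave 6344 genes or more and the highest other gave 0, in TA against model 1 of 10 gave 3031 and the highest other 0, and in TA against normal 1 of 10 gave 2081 and the highest other 0. For lists, 2 of 10 splits gave 22 or more in model against normal (highest other 22), 1 of 10 gave 22 in TA against model (highest other 21) and 2 of 10 gave 18 in TA against normal (highest other 18). The preset-correlation list counts were therefore equalled or nearly equalled by groupings that mix the groups. For the genes that changed in opposite directions, 1 of 100 drawn splits of the 9 libraries, the real one, gave 2620 or more. The highest other gave 1319 and the median other 0. Splits that mix unlike groups widen the spread within groups and so give few calls. The rank of the real split thus shows only that the groups differ. How much of the count rests on the shared model libraries stays open.

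In TA against normal, 5 of 6 clock genes that peak late at night or in the early morning were lower (median -2.08) and 10 of 11 that peak in the day or early evening were higher (median 2.32), with an exact permutation p = 0.00824 over 12376 arrangements. In model against normal 6 of 6 were lower (median -1.95), and 8 of 11 higher and 1 lower (median 1.70, exact permutation p = 0.0063), while in TA against model 0 of 6 were lower and 1 higher (median -0.18) and 7 of 11 higher (median 1.41, p = 0.0017). The clock genes are not independent of each other, so these permutation p-values overstate the evidence. With library totals the medians were -1.97 and 2.40 in TA against normal, -1.26 and 2.39 in model against normal and -0.75 and 0.80 in TA against model. For TA against normal a different share of hepatocyte RNA was argued against, since the hepatocyte markers had a median of -0.0871 there, with 0 of 30 called by edgeR, although the list was called lower without TA replicate 3 (adjusted p = 0.0122, range 0.0122 to 0.805), and in model against normal that median was -1.29 with 26 of 30 called. Livers collected at different times of day may explain the pattern, as may an effect of diet or TA on the clock, which was not tested, and the labels give no time of collection.

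In TA against model, hepatocyte markers were higher and macrophage markers lower. A single change in the share of hepatocyte RNA was argued against, since the medians of 8 lists of other cell types ranged from -1.14 (neutrophils) to 0.05 (B cells), with a permutation p = 2.0e-05 over 186 genes, or 0.0015 without the B cell list, though genes of a list are not independent. Library totals took the hepatocyte median from 1.14 to 0.565 and the macrophage median to -1.641. Scaling shifts both alike, so only the hepatocyte sign, which held, was tested. A change by TA in several cell types or in hepatocyte state stays open and was not tested.

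In model against normal, male-biased liver genes were lower and female-biased genes higher. Model libraries of only female mice were argued against, since 4 Y-linked genes stood at 66.4% to 71.4% of the normal mean in each. The TA libraries stood at 61.8% to 95.6%. Pools with some female mice were not excluded, since the labels do not say that each library came from a separate mouse. A lower share of hepatocyte RNA as the whole cause was argued against, since male-biased genes lay below the hepatocyte markers by -2.99 in median. The medians were -4.29 against -1.29, with a permutation p = 1e-05, the smallest that 100000 permutations give. Genes of a list are not independent, so that p overstates the evidence. The female-biased median was 3.02, or 2.52 with genes at 0 set to their bound. A loss of the male pattern of hormone signals, brought by the diet, is a candidate explanation that was not tested.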
